A study of Mus musculus with 4 samples.

How the data were processed

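RNA was measured in 4 cultures of RAW 264.7, an established mouse macrophage-like cell line: 2 mock-infected and 2 infected with the Toxoplasma gondii strain RHΔku80 at a multiplicity of infection of 3 for about 24 h, per the labels' protocols. Total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared by the Affymetrix protocol and hybridised in 1 colour, per the labels' protocols. The deposited values were made with RMA, per the submitters' processing notes. RMA corrects the background of each array, brings the probe distributions of all arrays onto a common shape and summarises the probes of each probe set. The software and version behind RMA are not given in the sources used here, nor is a genome build, and no coordinates are therefore printed. The deposited values were read as log2 expression per probe set because all lie between 2.51 and 14.65, the span of a scanner on that scale, and none is below 0. No values before RMA were used here, so signal over background could not be set for a probe set, and values at the low end have no detection call. Quantile steps inside RMA force the arrays onto a like distribution, so a change shared by most genes would not be visible.

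Groups and replicate numbers were taken from the sample titles. The labels say that infections were done in duplicate but not whether the duplicates were separate experiments. The p-values of genes therefore measure only the spread between these samples, which may be technical. The 45101 probe sets were named through the platform annotation, and symbols were updated through their Entrez identifiers to those of the RefSeq gene table of assembly GRCm38.p6. Of these probe sets, 64 were array controls, 34945 carried 1 gene symbol, 932 carried several and 9160 were not listed with a gene. The identifiers of 34741 of the single-gene probe sets were found in the gene table and 204 were not, and those kept their older symbol. A gene was represented by its probe set with the highest mean over the 4 arrays, among probe sets with 1 symbol, which gave 18193 genes, of which 9010 had more than 1 probe set. No filter on level was applied. Of the 173 genes past the threshold, 85 had more than 1 probe set, and in 11 of these a further probe set had a difference of the opposite sign.

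Infected and mock arrays were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes at default settings on the deposited log2 values, with 2 residual degrees of freedom before moderation. P-values were 2-sided and adjusted over all genes by Benjamini-Hochberg, with a threshold of 0.05. No batch or replicate term was used. A log2 difference is the infected mean minus the mock mean, its error is the moderated standard error (SE), and group levels are mean ± SD over 2 arrays. On simulated data with 200 changed genes among 18193, the same steps recovered 76% of 2-fold and 99% of 4-fold changes with 9 false calls. With the infected arrays made as unequal as the real ones, they recovered 72% and 98% with 3 false calls. Both simulations drew gene variances from the distribution that limma had fitted, with noise independent over genes. They therefore check the steps, not whether the real arrays follow that model.

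Before the data were examined, 36 gene lists were fixed, covering MYC, growth, metabolism, the cell cycle, interferon and inflammatory genes, stress responses, macrophage identity, reference genes and markers of other cell types. Of 805 gene names written singly in these lists, 731 had a gene row. The histone list had been written with older names that matched none of the current symbols, so names were also looked up among synonyms after this was seen, which also changed how many genes other lists matched. Lists were tested against all other genes with limma camera at a preset inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 36 lists. At this preset the p-value of a list rests on the spread over genes, not between cultures. Camera with an estimated correlation, camera on ranks and the rotation test fry were run as alternatives. With an estimated correlation, camera works from 2 residual degrees of freedom here, and none of the list calls held, with the lowest adjusted p = 0.22. At an unadjusted p below 0.05 that setting gave 5 lists higher and 2 lower. Over the lists called at the preset, the estimated correlation ran from -0.07 (dendritic cells) to 0.13 (ATF4). Fry, which does not compare a list with other genes, called 7 lists higher and 0 lower, and 2 lists lower at an unadjusted p below 0.05. A range of adjusted p given for a list covers its other alternatives.

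The genes named in the text were chosen by a rule fixed before the data were examined. It took Myc, the 12 largest rises and up to 12 largest falls among genes past the threshold whose groups did not overlap, without uninformative symbols, and up to 4 members of each list with the smallest p. Genes named outside the rule are marked as chosen after their values were seen. Alternatives fixed beforehand were other scalings of the arrays, filters on dim genes, other treatments of several probe sets, other variance models, the replicate number as a block, each array left out in turn, a stricter threshold, limma treat against a 1.2-fold minimum and the other list tests. Array weights, a crossed pairing of the replicates and lists without the members of the STAT6/STAT3 list were added after the data had been seen. With an array left out, the lone array of its group is assumed to vary like the other group. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.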

Results

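Transcript levels were measured on 4 arrays of RAW 264.7 cells, a mouse macrophage-like line derived from a tumour induced by Abelson leukaemia virus. In 2 cultures the cells were mock-infected, and in 2 they were infected for about 24 h with Toxoplasma gondii, an obligate intracellular parasite, at a multiplicity of infection of 3. The parasite strain, RHΔku80, is a type I RH line lacking Ku80, a gene of non-homologous end joining whose loss makes targeted gene replacement easier. The log2 values of each array had a median between 4.83 and 4.86. The number of arrays limits the precision of every value below.

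The comparison of infected with mock cultures asks which host transcripts change during infection. Infected cells carried far more transcript of a set of chemokines, receptors and enzymes. Ccl22, which encodes a chemokine ligand of CCR4, rose 170-fold, from 4.53 ± 0.060 to 11.94 ± 0.0077 (log2, mean ± SD, n = 2 arrays per group), with a log2 difference of 7.41 (SE 0.11, limma adjusted p = 4.00e-06). Ccl17, the gene of another CCR4 ligand, rose 33.2-fold (log2 difference 5.05, SE 0.14, adjusted p = 4.20e-05), and Arg1, the gene of arginase 1, rose 20.8-fold (log2 difference 4.38, SE 0.13, adjusted p = 4.43e-05). Among genes past the threshold, falls were fewer and smaller. The gene with the largest fall past the threshold was Ms4a6b, of the membrane-spanning MS4A family, at a log2 difference of -1.11 (SE 0.15, adjusted p = 0.0287).

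Of 18193 genes tested, 163 rose and 10 fell at the 0.05 threshold on the adjusted p. At least 2-fold differences were found for 129 of the rises and 3 of the falls. At an unadjusted p below 0.05, 825 genes were higher and 1050 lower. In all 173 genes past the threshold, both infected arrays lay on the same side of both mock arrays, which was true of 43.2% of all genes, where chance gives 33.3% with 2 arrays against 2. In 68 of the 163 genes that rose, the mock mean lay below the mean of the array medians, here taken over the 18193 genes and not all probe sets. The array compresses differences at low levels, so folds of these genes may be understated. The median difference of all genes was -0.01.

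Infected replicate 2 differed from the other 3 arrays in its control probe sets. Its spiked hybridization controls lay 2.58 log2 units and its spiked poly-A controls 4.06 log2 units above the mean of the others, and its 18S ribosomal RNA sets 1.40 above. The trpn sets, which are not spiked, lay 0.18 above. The difference between the infected arrays also had a wider spread over genes (SD 0.30) than the difference between the mock arrays (SD 0.161), and exceeded 0.5 in 9.49% of genes against 0.753%. Without infected replicate 2, 234 genes were higher and 21 lower, and 170 of the 173 genes past the threshold remained. Without infected replicate 1, 1248 were higher and 1477 lower. Without mock replicate 1 the counts were 60 and 0, and without mock replicate 2 they were 74 and 0, with 252 and 192 genes lower at an unadjusted p below 0.05 in limma.

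**Figure D1:**
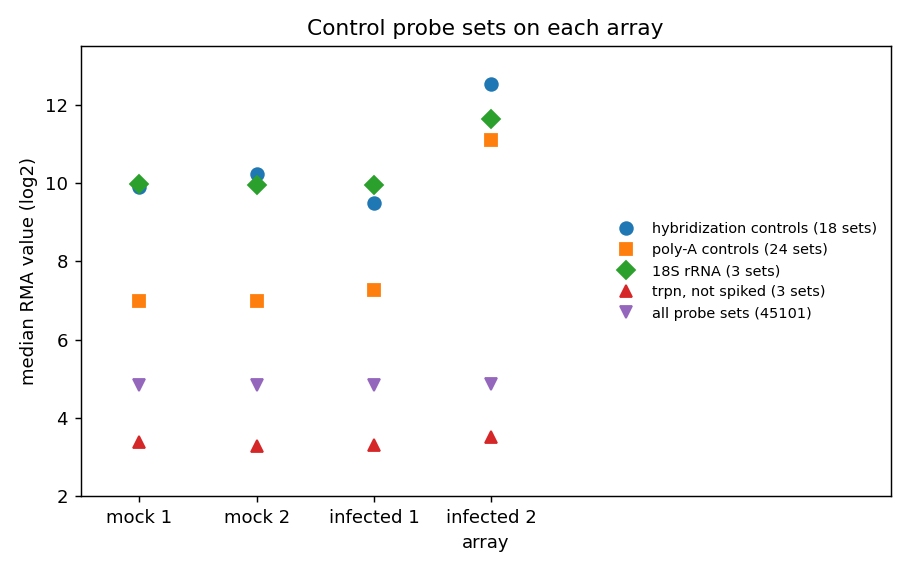
Median log2 value (y axis) of each kind of control probe set and of all probe sets on each of the 4 arrays (x axis), with 1 symbol per kind. On infected replicate 2 the poly-A controls reach 11.1 and the hybridization controls 12.5, against at most 7.27 and 10.2 on the others, while the median of all probe sets stays at 4.86.

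**Figure D2:**
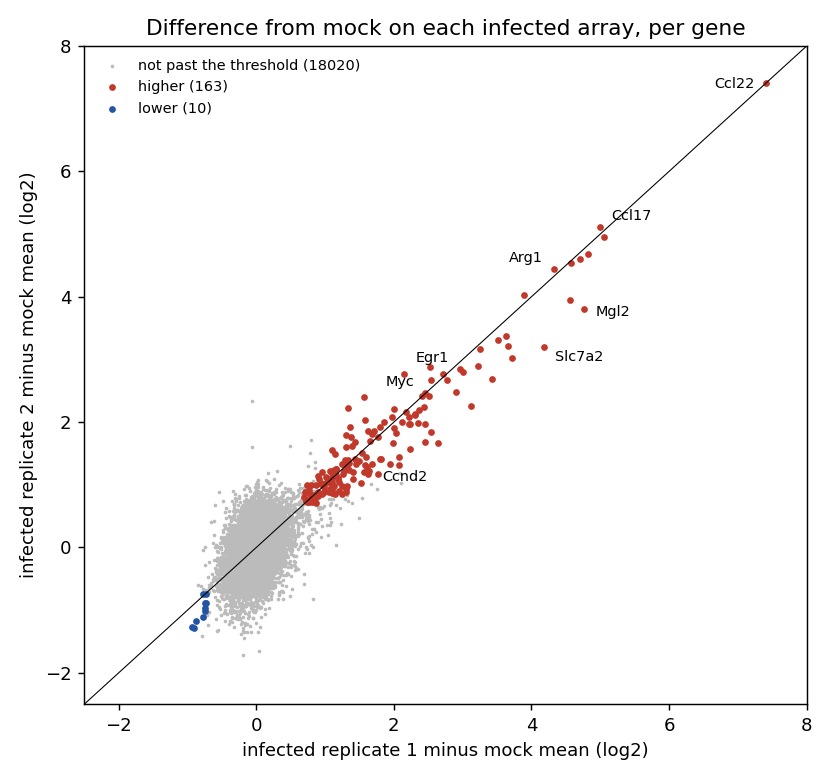
Each point is 1 of 18193 genes, with its log2 difference from the mock mean on infected replicate 1 (x axis) and on infected replicate 2 (y axis), and the line marks equal values. The 163 genes that rose lie along the line up to Ccl22 at 7.41, while the 10 genes that fell lie at or above -1.28 on both arrays, and genes not past the threshold spread further along the y axis.

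The 12 largest rises spanned 11.3-fold to 170-fold, and all 12 stayed past the threshold in the alternatives run on each of them (13 or 14 per gene), with a highest adjusted p of 0.00846. Besides Ccl22, Ccl17 and Arg1 they included Ccl2, the gene of a monocyte-attracting chemokine, at 4.56, and Ccl24, the gene of the eosinophil-attracting chemokine eotaxin-2, at 3.96. Surface receptors among them were Olr1, a receptor for oxidised lipoprotein, which rose 32.0-fold, Ccr7, a receptor for lymph node homing, at 4.75, and Mgl2, a galactose-binding lectin, at 4.29. Hbegf, which encodes an EGF receptor ligand, reached 4.65, the arginine transporter gene Slc7a2 3.69, and Serpinb6b, a serine protease inhibitor gene, 3.50. Marcks, which encodes a protein kinase C substrate, had a difference of 4.25, with 0.47 to 5.91 over its probe sets. The probe sets of Slc7a2 ranged from 0.19 to 3.69, with a mean difference of 1.36, and those of Hbegf from 2.82 to 4.65.

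The 10 genes that fell had log2 differences from -0.73 to -1.11. They included Gas6 at -1.09, the gene of a ligand of the receptor kinases Axl and Mertk, Neurl1b at -1.02, a ubiquitin ligase gene, and Dbp at -0.95, a transcription factor gene of the circadian clock. A pair of sialyltransferase genes was among them, St3gal5, which makes the ganglioside GM3, at -0.88 and St3gal6 at -0.80. The others were Fgd2 at -0.85, Kank3 at -0.82, P2ry6, a receptor gene for UDP, at -0.76 and Ambp at -0.73. All 10 missed the threshold without mock replicate 1 (adjusted p from 0.202 to 0.760) and without mock replicate 2 (0.211 to 0.609), and also when every probe set was tested (0.0605 to 0.107). Further probe sets of Ms4a6b, Gas6, St3gal6 and Kank3 reached -0.26, -0.08, 0.08 and 0.08. With the mean of a gene's probe sets these 4 differed by -0.68, -0.59, -0.34 and -0.40 and missed the threshold, as did Dbp at -0.81 (adjusted p from 0.0754 to 0.322). Dbp (0.0516) and Kank3 (0.0594) also missed it with an intensity trend, and Dbp, St3gal5, Fgd2 and Ambp with robust eBayes (0.0518 to 0.0523).

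The MYC lists ask whether host c-MYC and genes it regulates differ in Toxoplasma-infected cells. They were put first because this series is known to have been used for host c-Myc in Toxoplasma infection. Their choice, though fixed before the data were examined, was therefore not blind to that use. Myc, which encodes the c-MYC transcription factor, rose 5.50-fold, from 5.76 ± 0.25 to 8.22 ± 0.012 (mean ± SD, n = 2 arrays per group), with a log2 difference of 2.46 (SE 0.15, limma adjusted p = 0.000999). Its call held under all 14 alternatives, with adjusted p from 1.12e-07 to 0.00438. Myc was the only 1 of the 11 measured genes of the MYC family network past the threshold, also when adjusted over the list alone, and the list did not shift (camera adjusted p = 0.601, median -0.04). Among its partners and antagonists, Mlx differed by -0.34, Mxi1 by 0.27 and Mxd4 by -0.29, none past the threshold. The 2 probe sets of Mxi1 differed by -0.57 and 0.27, so its sign depends on the probe set.

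Of 34 measured genes of the MYC-regulated growth list, 1 rose and 33 did not pass the threshold, and 2 rose when adjusted over the list alone. At an unadjusted p below 0.05 in limma, 4 were higher and 2 lower. The one that rose was Ccnd2, which encodes cyclin D2, at 1.45 (SE 0.17, adjusted p = 0.0166), with 0.38 to 1.54 over its probe sets. It missed the threshold without mock replicate 1 (adjusted p = 0.116), the highest of a range from 0.000145. Odc1, the gene of the first enzyme of polyamine synthesis, had a difference of 0.67 and missed the threshold (adjusted p = 0.104). Odc1 passed it without infected replicate 1 (adjusted p = 0.0259) and without infected replicate 2 (0.036), in a range over alternatives from 0.0177 to 1.00. The median of the list was -0.01 (camera adjusted p = 0.944), at 0.01 on infected replicate 1 and -0.05 on infected replicate 2. Ribosome biogenesis (0 of 40 measured genes past the threshold, camera adjusted p = 0.991) and cytosolic ribosomal proteins (0 of 46, adjusted p = 0.991) did not shift either. At an unadjusted p below 0.05 in limma, 1 ribosome biogenesis gene was higher and 1 lower, and 0 ribosomal protein genes. Many ribosomal protein sets were bright in mock cells, such as Rpl19 at 13.74 and Rps29 at 13.92, while others were dim, such as Rps16 at 3.44. The highest value on mock replicate 1 was 14.37, so a rise of the bright sets could have been missed.

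**Figure D3:**
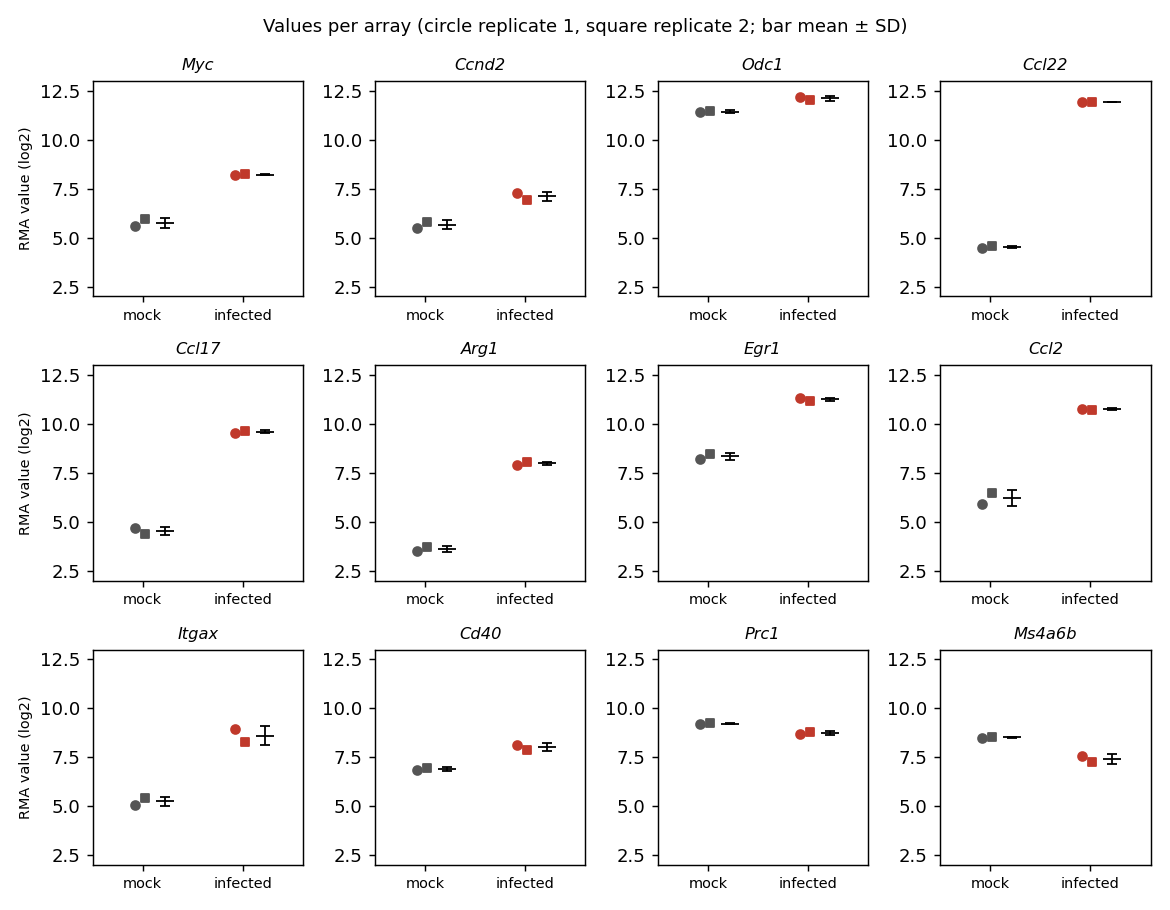
Log2 values of 12 genes on each array, with mock in dark grey, infected in red, replicate 1 as circles, replicate 2 as squares, and the mean ± SD of each group beside them. Myc moves from 5.76 to 8.22 and Ccl22 from 4.53 to 11.94, while Odc1 and Prc1 differ by 0.67 and -0.48 without passing the threshold.

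The list of STAT6 and STAT3 targets and alternative activation shifted most. Of 33 measured members, 18 rose, 0 fell and 15 did not pass, or 22 rose and 1 fell when adjusted over the list alone. Its median was 1.07, at 1.16 on infected replicate 1 and 1.09 on infected replicate 2 (camera adjusted p = 3.63e-37), with an adjusted p = 0.22 with an estimated correlation. Ccl22, Ccl17, Arg1 and Ccl24 were its members with the smallest p.

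Of 46 measured NF-kB and inflammatory mediators, 16 rose and 30 did not pass, or 29 rose when adjusted over the list alone. The median was 0.69, at 0.67 on each infected array (camera adjusted p = 2.28e-21, and adjusted p = 0.22 with an estimated correlation). Ptgs2, the gene of the inducible cyclooxygenase, rose 6.09-fold (log2 difference 2.61, SE 0.13, adjusted p = 0.000379). Csf1, the gene of the macrophage growth factor, rose 4.84-fold, with -0.0047 to 2.27 over its probe sets and a difference of 1.15 for their mean, and the chemokine gene Ccl5 rose 3.89-fold.

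Immediate-early genes and feedback regulators of MAP kinase signalling were also higher, with 11 of 32 measured members that rose and 21 that did not pass, or 17 that rose when adjusted over the list alone. The median was 0.43, at 0.39 on infected replicate 1 and 0.54 on infected replicate 2 (camera adjusted p = 9.31e-17, and adjusted p = 0.22 with an estimated correlation). Egr2 rose 10.8-fold (log2 difference 3.44, SE 0.17, adjusted p = 0.000416) and Egr1 7.49-fold (log2 difference 2.90, SE 0.14, adjusted p = 0.000351), both zinc finger transcription factor genes. The phosphatase genes Dusp2 and Dusp5 rose by 2.17 and 2.03.

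Of 13 measured genes of MHC class II presentation, 1 rose, and 7 rose when adjusted over the list alone, while 12 had a difference above 0. The list's median was 0.35, at 0.38 on infected replicate 1 and 0.43 on infected replicate 2 (camera adjusted p = 6.17e-07, and adjusted p = 0.22 with an estimated correlation). The gene that rose was Cd40, a co-stimulatory receptor rather than a presenting molecule, at 1.11 (adjusted p = 0.0221). Cd40 missed the threshold without mock replicate 1 (adjusted p = 0.248) and without mock replicate 2 (0.143), in a range over alternatives from 0.00106 to 0.248. Cd86 differed by 1.15 (adjusted p = 0.0974), and its adjusted p was 0.0421 without mock replicate 2 and 0.037 without infected replicate 1, in a range from 0.00171 to 0.464. H2-Ab1 and Cd80 each differed by 0.57, with -0.01 to 0.57 and 0.04 to 0.57 over their probe sets. H2-Ab1 was dim in mock cells, with a mean of 4.58, below the median of every array, and had an infected mean of 5.15. MHC class I presentation did not shift (0 of 12 past the threshold, 0 also at an unadjusted p below 0.05 in limma, camera adjusted p = 0.991), with Tapbp at -0.15.

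None of 37 measured type I interferon-induced genes passed the threshold, and at an unadjusted p below 0.05 in limma 1 was higher and 5 lower (median -0.08, camera adjusted p = 0.182). The list passed with the mean of a gene's probe sets (adjusted p = 0.0356) and with every probe set tested (0.0169), in a range up to 0.812 without mock replicate 2. Cxcl10 differed by 0.93, Oasl2 by -0.80, Rtp4 by -0.58 and Xaf1 by -0.42. Cxcl10 missed the threshold in the main fit (limma adjusted p = 0.110) but reached 0.0114 under an alternative that kept all arrays. Of 11 measured GTPases induced by interferon-gamma, a family that acts on the parasite's vacuole, none passed, and 1 was higher and 1 lower when adjusted over the list alone, Gbp2b at 0.62 and Ifi47 at -0.60 (camera adjusted p = 0.991). The SE of both differences was 0.11. Gbp2b was dim, with a mock mean of 3.79 and an infected mean of 4.41, both below the median of every array.

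The G2/M and G1/S lists were lower with a preset correlation and missed the threshold with an estimated correlation (camera adjusted p = 0.22 for both), with no member past the threshold. Of 31 measured G2/M and mitosis genes, 26 were below 0, and 12 were lower and 0 higher at an unadjusted p below 0.05 in limma. The median was -0.28, at -0.31 on infected replicate 1 and -0.22 on infected replicate 2 (camera adjusted p = 2.27e-07). Plk1, a mitotic kinase gene, and Prc1, a gene of the central spindle, each differed by -0.48, Ccnb2 by -0.38 and Cdca3 by -0.37. With fry the G2/M list missed the threshold (adjusted p = 0.092, in a range from 1.84e-11). Of 35 G1/S and DNA replication genes, 29 were below 0, with Gins2 at -0.50, Tk1 at -0.48 and Dscc1 at -0.61, and 10 were lower and 1 higher at an unadjusted p below 0.05. The median was -0.17 (camera adjusted p = 0.000237), and the call was lost without infected replicate 1 (adjusted p = 0.0528, in a range over alternatives from 2.70e-06) and with fry (0.0609). Replication-dependent histones did not shift (0 of 11, 1 lower at an unadjusted p below 0.05, camera adjusted p = 0.741), with H2bc21 at -0.75. Whether the labelling captures these histone transcripts was not checked, so this list was not read for or against the lower cell-cycle lists.

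Of 81 measured subunits of oxidative phosphorylation, 64 were below 0 and none passed the threshold, with 1 higher and 2 lower at an unadjusted p below 0.05 in limma. The median of this list was -0.10, at -0.08 on infected replicate 1 and -0.10 on infected replicate 2 (camera adjusted p = 0.00496, and adjusted p = 0.471 with an estimated correlation). The call was lost without mock replicate 2 (adjusted p = 0.0812) among genes above the median level (0.181) and with fry (0.142), in a range from 0.000184. Random lists matched on mean level had a median of -0.06, with a central 95% from -0.09 to -0.01. Sdhb differed by -0.32 and Sdhc by -0.30. Glycolysis and HIF-1 targets (0 of 32, camera adjusted p = 0.67) and cholesterol biosynthesis (0 of 20, adjusted p = 0.67) did not shift, with Pfkm at -0.48, Ero1a at 0.48 and Idi1 at 0.43. At an unadjusted p below 0.05 in limma, 3 glycolysis and HIF-1 genes were higher and 2 lower, and 2 cholesterol genes were higher. Of 17 genes of fatty acid synthesis and LXR targets, 1 rose (camera adjusted p = 0.998), the cholesterol exporter gene Abca1 at 0.84 (adjusted p = 0.0378), which missed the threshold without mock replicate 1 (0.299) and mock replicate 2 (0.584). It also missed it with the mean of its probe sets (difference 0.46, adjusted p = 0.228), which ranged from 0.15 to 0.84, and with every probe set tested (0.0806). The range for Abca1 started at 0.00920, and its relative Abcg1 differed by -0.57 (adjusted p = 0.140).

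The ATF4 and amino acid response list was higher, with 2 of 39 measured members that rose, also when adjusted over the list alone, and 29 above 0. Its median was 0.16, at 0.14 on infected replicate 1 and 0.10 on infected replicate 2 (camera adjusted p = 0.000114, and adjusted p = 0.501 with an estimated correlation). The genes that rose handle cysteine: Cth, which encodes cystathionine gamma-lyase, at 1.42 (adjusted p = 0.00594) and the cystine transporter gene Slc7a11 at 1.35 (adjusted p = 0.00643). Cth missed the threshold without mock replicate 2 (0.0680, range from 5.40e-05) and Slc7a11 without mock replicate 1 (0.0871, range from 9.35e-05). With fry the list missed it as well (adjusted p = 0.116, range from 9.35e-06).

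Of 13 measured genes of polyamine and arginine metabolism, 3 rose, Arg1, Slc7a2 and Arg2, and 4 when adjusted over the list alone. These 3 take up or cleave arginine, and Arg2 differed by 0.73 (adjusted p = 0.0483). Arg2 was dim, with a mock mean of 3.45 and an infected mean of 4.18, both below the median of every array. Without detection calls, its presence could not be set. The list's median difference was 0.14, at 0.10 on infected replicate 1 and 0.06 on infected replicate 2 (camera adjusted p = 0.00161, and adjusted p = 0.262 with an estimated correlation). The call was lost without infected replicate 1 (0.151), on ranks (0.19), with fry (0.0502), among genes above the median level (0.325, with a median of 0.0084) and without the members shared with the STAT6/STAT3 list (0.325), the highest of a range from 4.09e-07. Arg2 missed the threshold without mock replicate 1 (0.688) and without mock replicate 2 (0.651), with the mean of its probe sets (0.161), with every probe set tested (0.105), with centred arrays (0.0524) and with robust eBayes (0.0511), in a range from 0.016.

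Of 20 measured p53 targets, 3 rose, Gadd45a at 1.51, Plk2 at 1.35 and Plk3 at 1.17, and 5 when adjusted over the list alone, while Cdkn1a, the gene of the p53-induced inhibitor p21, differed by 0.47 (adjusted p = 0.255). The list had a median of 0.06, at 0.02 on infected replicate 1 and 0.18 on infected replicate 2 (camera adjusted p = 0.00182, and adjusted p = 0.262 with an estimated correlation). The call was lost on ranks (0.10) and with fry (0.0502), in a range from 0.000318. Without mock replicate 1, Gadd45a (0.0814, range from 4.80e-05), Plk2 (0.0505, range from 8.51e-05) and Plk3 (0.113, range from 0.000391) missed the threshold, and without mock replicate 2 Plk2 (0.0691) and Plk3 (0.113) did. The probe sets of Plk2 ranged from 0.12 to 1.35, and their mean differed by 0.73.

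Of the remaining stress and maintenance lists, that of apoptosis regulators lay close to the threshold. Among its 22 measured members Fas, the gene of a death receptor, rose by 1.33 and the caspase gene Casp4 by 0.89, and 6 rose and 1 fell when adjusted over the list alone. The list missed the threshold (camera adjusted p = 0.0577, and adjusted p = 0.413 with an estimated correlation) but passed it, towards higher values, in 11 of 18 camera alternatives, from 0.0144 with every probe set tested. These included centred arrays (0.0491), quantile normalization (0.0198), the replicate block (0.0275), and the fits without mock replicate 2 (0.0316) and without infected replicate 2 (0.0287). With fry the list passed too, towards higher values (adjusted p = 0.0016). Its median was 0.04, and -0.0034 among genes above the median level and with the dimmest genes left out, where the list passed as well (0.0204 and 0.0416). Of 13 iron handling genes, Cp, which encodes ceruloplasmin, rose by 1.15 (list adjusted p = 0.944), with 3 higher and 1 lower when adjusted over the list alone. With every probe set tested the iron list passed (0.00733, in a range up to 0.99, with a median of 0.07 against -0.09 with 1 probe set per gene). Fas, Casp4 and Cp each missed the threshold without mock replicate 1 (0.136, 0.337 and 0.171) and without mock replicate 2 (0.17, 0.337 and 0.0921), in ranges from 0.000253, 0.00484 and 0.000552. With every probe set tested Fas (0.0530) and Casp4 (0.0507) missed it too. No gene passed among 23 of ER stress (adjusted p = 0.998), 17 heat shock chaperones (0.421), 20 NRF2 and redox genes (0.944), 31 of lysosome and autophagy (0.991) or 12 constitutive reference genes (0.642). At an unadjusted p below 0.05 in limma, 2 of the chaperones, 2 of the NRF2 and redox genes and 1 of the lysosome genes were higher, 1 NRF2 and 1 lysosome gene were lower, and 0 of the ER stress and reference genes passed. Hspa5 differed by 0.32, Hspa9 by 0.36, Hmox1 by 0.57, Psap by 0.32 and B2m by -0.14.

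Among 42 measured genes of macrophage identity and receptors, 3 rose, and 4 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.959). Itgax, which encodes the integrin CD11c, rose 10.3-fold (log2 difference 3.37, SE 0.24, adjusted p = 0.00175), Ccr1 rose by 0.97 and the scavenger receptor gene Cd36 by 0.86. Cx3cr1 differed by -0.85 (adjusted p = 0.0819), at -0.68 on infected replicate 1 and -1.03 on infected replicate 2. Ccr1 and Cd36 missed the threshold without mock replicate 1 (0.171 and 0.375) and mock replicate 2 (0.453 and 0.442), and with every probe set tested (0.0750 and 0.0632), and their ranges started at 0.00227 and 0.00566. The probe sets of Ccr1 ranged from 0.18 to 0.97, and with their mean it differed by 0.58 and missed the threshold (0.0890). The signs of median, mean and test direction were not the same in this list, nor in both MYC lists, both ribosomal lists, fatty acid synthesis, ER stress, NRF2, iron, lysosome or T and NK cells, none of which passed the threshold.

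Of the marker lists of other cell types, those of dendritic cells and osteoclasts were higher. Of 9 dendritic cell genes 3 rose, also when adjusted over the list alone, Ccr7 at 4.75 and the transcription factor genes Batf3 at 1.36 and Zbtb46 at 0.90 (camera adjusted p = 1.03e-05, and adjusted p = 0.22 with an estimated correlation, median 0.29, at 0.23 on infected replicate 1 and 0.34 on infected replicate 2). Of 11 osteoclast genes 3 rose, Ocstamp, needed for cell fusion, at 2.71, the proton pump subunit gene Atp6v0d2 at 2.15 and the phosphatase gene Acp5 at 1.11, and 4 when adjusted over the list alone (median 0.21, at 0.12 and 0.26 on the same arrays, camera adjusted p = 0.000418, adjusted p = 0.362 with an estimated correlation, and 0.161 on ranks). RAW 264.7 cells can themselves form osteoclasts. Without mock replicate 1, Batf3 (adjusted p = 0.0840), Zbtb46 (0.513) and Acp5 (0.111) missed the threshold, and without mock replicate 2 Zbtb46 (0.241) and Acp5 (0.166) did, in ranges from 7.77e-05, 0.00576 and 0.0007. Zbtb46 also missed it with the mean of its probe sets (0.52, adjusted p = 0.196), which ranged from 0.21 to 0.90, and with every probe set tested (0.0695). No marker passed in the lists of fibroblasts (0 of 16, camera adjusted p = 0.642), T and NK cells (0 of 12, 0.959), B cells (0 of 9, 0.284), neutrophils (0 of 9, 0.959) or epithelium (0 of 9, 0.642), where at an unadjusted p below 0.05 in limma 1 epithelial gene was higher, 1 neutrophil and 1 T and NK gene were lower, and 0 fibroblast or B cell genes passed.

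**Figure D4:**
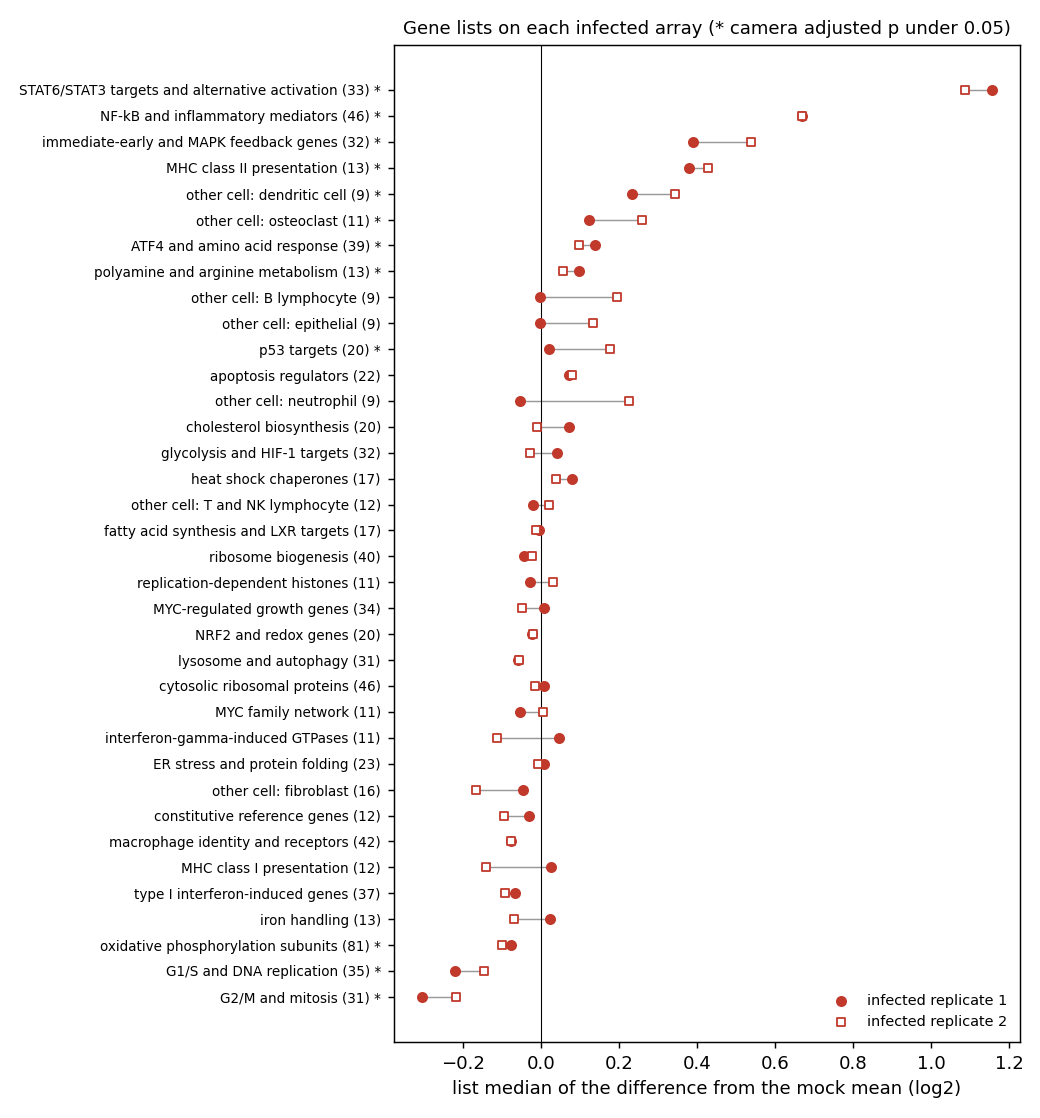
Median log2 difference from the mock mean of each of the 36 gene lists on infected replicate 1 (filled circles) and infected replicate 2 (open squares), with the number of measured genes in brackets and an asterisk where the camera adjusted p was below 0.05. The STAT6/STAT3 list lies at 1.16 and 1.09, and the G2/M list at -0.31 and -0.22.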

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

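Of the tests below, those on the spiked controls, on RNA integrity and on parasite RNA were chosen after the control values had been seen. The conditions for less mouse RNA and for parasite RNA were changed again after all values were known, and the changed conditions left both undecided. The test on genes lower on 1 array was set before its result, but the interval it had to clear was added after. Control probe sets, which the comparison of genes leaves out, stood apart on infected replicate 2: relative to the mean of the other 3 arrays, the 18 spiked hybridization controls lay 2.58 log2 units higher, the 24 spiked poly-A controls 4.06 higher and the 3 sets for 18S ribosomal RNA 1.40 higher. Probe sets that carry several gene symbols or are not listed with a gene were tested apart from the named genes, and 13 of 10092 were higher in infected cells and 0 lower in limma, with differences of 3.57 for a probe set with several symbols and 2.72 for one not listed with a gene as the largest.

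A candidate explanation for the controls is less mouse RNA relative to the spikes on infected replicate 2, which stays open, since the controls that raised it, hybridization at 2.58 (95% bootstrap interval over probe sets 1.83 to 3.03), poly-A at 4.06 and trpn at 0.18, cannot also test it, and the unspiked 18S sets lay 1.40 higher. A larger parasite share, as in any culture infected at this ratio, cannot be told apart. On infected replicate 1 the hybridization controls lay at -0.49 relative to the mock mean (95% bootstrap interval over probe sets -0.58 to -0.41). The poly-A controls lay at 0.43 relative to the mock mean on that same 1 array. A larger share in the other infected culture alone stays open, untested. Lower RNA integrity cannot be told apart, since the 3' minus 5' gap was 0.44 wider than on the other arrays for Actb and 0.15 for Gapdh, between the bounds set. Of 1137 genes at least 0.5 lower on infected replicate 2 than on mock replicate 1 (median -0.61), the median on the other pair of arrays was -0.15, or 24.0% of it (interval over genes 21.1 to 28.0). Whether these genes deviate on that array alone cannot be told apart, since that interval lies on both sides of the bound set. Genes picked as lower on infected replicate 1 than on mock replicate 1 gave 28.2%. Genes picked as lower on mock replicate 2 than on mock replicate 1 gave 20.03%, read on infected replicate 1 minus infected replicate 2. The order of that last pair is arbitrary, so this share is no baseline. Among genes picked as higher, the shares were 25.2% for infected replicate 2 and 82.2% for infected replicate 1, a contrast that was not tested.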

How the results depend on the processing

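The array weights, the crossed pairing and the lists without STAT6/STAT3 members were chosen after the data had been seen. No named gene or list past the threshold changed direction under an alternative run on it. Of the 50 named genes past the threshold, all kept their call without infected replicate 1, without infected replicate 2, with array weights, with quantile normalization and with the replicate block, 26 lost it without mock replicate 1 and 23 without mock replicate 2. With every probe set tested 17 lost it, with the mean of a gene's probe sets 9, with robust eBayes 5, with an intensity trend 2 and with centred arrays 1. Of 106 named genes that missed the threshold, 53 passed it without infected replicate 1, where the lone infected array is assumed to vary like the mock pair. With 1 array left out, genes higher ranged from 60 (without mock replicate 1) to 1248 (without infected replicate 1), genes lower from 0 to 1477, genes at least 2-fold higher from 60 to 152 and genes at least 2-fold lower from 0 to 76. The mean of a gene's probe sets gave 1 gene at least 2-fold lower. With every probe set tested, 0 were lower and 0 at least 2-fold lower, with 1890 lower at an unadjusted p below 0.05. Genes lower numbered 16 with an intensity trend and 6 with robust eBayes. At an adjusted p below 0.01, 78 genes were higher, 78 of them at least 2-fold, and 0 were lower, 0 of them at least 2-fold. With limma treat 0 were lower and 0 at least 2-fold lower, with 149 lower at an unadjusted p below 0.05. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 0 lower, with 5, 2 and 2 lists at an unadjusted p below 0.05. Beyond fewer arrays, stricter thresholds and more probe sets tested, the cause was not tested. With the replicate number as a block, 228 genes were higher and 29 lower. Deviations of arrays with the same number correlated at -0.15 across genes, which are not independent replicates, so a pairing was not established. The crossed pairing gave 183 genes higher and 11 lower. Array weights gave 190 and 14, but gave both infected arrays the weight 0.529, so they could not set 1 infected array against the other. Signal over background was not given by RMA values, which limits what can be said of dim genes.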

Other observations

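The tests on infected replicate 2 in the MYC and cell-cycle patterns, the gene families and the genes in the first paragraphs were chosen after their results or values had been seen. Of the 163 genes that rose, 97 were in none of the fixed lists. Ligands of the inhibitory receptor PD-1 were among them. Cd274, the gene of PD-L1, rose 3.45-fold (log2 difference 1.79, SE 0.12, limma adjusted p = 0.00136) and kept its call with each array left out (0.000926 to 0.0163). Pdcd1lg2, the gene of PD-L2, rose 3.96-fold (log2 difference 1.99, SE 0.26, adjusted p = 0.0256), and missed the threshold without mock replicate 1 (0.0896) or mock replicate 2 (0.0964), in a range from 0.000411. Tnfrsf9, the gene of the co-stimulatory receptor 4-1BB, rose 5.34-fold, Mmp12, the gene of macrophage elastase, 8.33-fold, and Tgm2, the gene of tissue transglutaminase, 6.69-fold, and these 3 kept their calls with each array left out, with a highest adjusted p of 0.00365. Csf2rb, the gene of the shared receptor chain for GM-CSF, IL-3 and IL-5, rose 2.71-fold, with an adjusted p of 0.0503 without mock replicate 1 in a range from 0.0021.

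Of 225 gene families formed by symbol stem, 2 held more genes that rose than the 161 in 16331 background genes would give (one-sided Fisher's exact test, adjusted over families). The chemokine family Ccl had 6 of 18 measured members that rose, where 0.177 were expected (adjusted p = 3.17e-06), 7 and 8 with centred and with quantile-normalized arrays, 5 without mock replicate 1, 5 without mock replicate 2, 10 without infected replicate 1 and 7 without infected replicate 2. Ccl9, at 0.81, missed the threshold without mock replicate 1 (0.449) and mock replicate 2 (0.540), in a range from 0.0147. The protease inhibitor family Serpinb had 4 of 18 (adjusted p = 0.00281), 4 under both other scalings, 3 without mock replicate 1, 3 without mock replicate 2 and 7 without infected replicate 1. The 4 were Serpinb6b, Serpinb9 at 2.20, Serpinb9b at 2.10 and Serpinb1a at 1.70. Serpinb1a missed the threshold without mock replicate 1 (0.215) and mock replicate 2 (0.091), in a range from 0.00362. Genes of a family can lie close together and share regulation, so they cannot be taken as independent draws.

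Mycn, a paralog of Myc singled out after its values were seen, had the brightest probe set of the array in mock cells, at 14.34, near the top of the scale, and at 14.30 in infected cells. Its other probe sets were far less bright, with mock means of 11.10 and 10.60. They differed by -0.28 (limma adjusted p = 0.651) and -0.46 (adjusted p = 0.456). The brightest set stood for Mycn in the MYC family network list, and the level of the transcript cannot be set from it.

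Myc rose 5.50-fold while the MYC-regulated growth genes did not shift. Their median of -0.01 lay at percentile 89.3 among 10000 random lists matched on mean level. Those random lists had a median of -0.06, with a central 95% from -0.12 to 0.01. Noise of infected replicate 2 hiding a shift is argued against by the growth genes' median of 0.0084 without that array. Its 95% bootstrap interval over genes, -0.04 to 0.07, rests on the other infected array alone. The interval leaves out the spread between cultures, so it does not bound a shift of these genes in infected cultures. Whether bright members could not rise further cannot be told apart. The dimmer members had a median of 0.0077 with an interval over genes from -0.16 to 0.19, a width added as a condition after the value was seen. The list's own median level in mock, 11.18, lay above 96.5% of all genes, so dimmer is meant relative to a bright list. A biological effect of infection that separates Myc from these genes stays open, untested.

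The G2/M and G1/S lists were lower with the preset correlation (camera adjusted p = 2.27e-07 and 0.000237), and with an estimated correlation each had an adjusted p of 0.22. For G2/M, a trend with signal level is argued against by percentile 0 of the G2/M median of -0.28 among 10000 random lists matched on mean level, whose central 95% ran from -0.14 to 0.02. Infected replicate 2 alone is argued against by infected replicate 1, on which the G2/M median lay -0.28 from the median of all genes. Its interval over genes, -0.32 to -0.25, rests on 1 infected array and leaves out the spread between cultures. With fry both missed the threshold (adjusted p = 0.092 for G2/M, in a range from 1.84e-11, and 0.0609 for G1/S, in a range from 2.70e-06), as did G1/S without infected replicate 1 (0.0528). Effects of infection, cell density or medium at harvest stay open, untested.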
